A study of Homo sapiens with 6 samples.

How the data were processed

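RNA sequencing libraries were made from 3 groups of human samples with 2 libraries each, which the design text calls biological replicates. The groups were peripheral blood mononuclear cells (PBMC, the starting population) and cells after reprogramming that were positive for the neural surface marker PSA-NCAM and either positive or negative for a green fluorescent protein (GFP). Per the labels' protocols, vectors of reprogramming factors were electroporated into PBMC, cells were held for 3 days with IL-2 and beads against CD3 and CD28, and were then placed on primary glia. These steps are attached to all samples, and which of them the PBMC libraries went through is not given in the sources used here. The promoter of the GFP and the species of the glia are not given in the sources used here either. RNA was extracted with Trizol and libraries were made with a Clontech SMARTer kit, per the labels' protocols.

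The authors deposited 1 table of FPKM (fragments per kilobase of transcript, scaled to the mapped fragments of the library) with 23624 rows and a column per library. TopHat and Cuffdiff and the builds hg19 and GRCh37 are named, without versions or roles, per the submitters' processing notes. The annotation and the library-size method are not given in the sources used here. FPKM are not counts, and low values were not whole multiples of a fixed step, so the depth of each library is unknown and no count test, counting interval or floor was used. An exact 0 can be a failed estimate. Among genes tested, 3409 had a 0 in at least 1 library, 95 genes of the table had a 0 beside a value above 100 FPKM, and the 11 widely expressed reference genes had 0 values of 0. Genes are therefore called listed at 0, and no fold is given against a group at 0 other than the fitted change on the log2(FPKM + 1) scale, which is no bound. Gene symbols are those of the table, and 530 of 540 gene list entries matched a row, older symbols included. Names of 28 rows had been turned into dates in the table, 2 of these names occurred more than once, and these rows were tested but not named. The number in the column name of 1 PBMC library differs from that in its label, so the library was kept in its group without a replicate number. The descriptions give 1 GFP-positive and 1 GFP-negative library a shared number and the other induced libraries different ones, and whether a number marks a donor is not given in the sources used here.

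Values were transformed as log2(FPKM + 1), on which the change of genes with low values is understated. Genes with at least 1 FPKM in at least 2 of the 6 libraries were kept, which left 13544. One linear model with a mean per group was fitted to the 6 libraries with limma 3.58.1 in R 4.3.3, with a trended prior for the spread. It had 3 residual and 3.10 prior degrees of freedom. The contrasts were the mean of both induced groups against PBMC, each induced group against PBMC, and GFP-positive against GFP-negative cells. P-values were adjusted by Benjamini and Hochberg over the genes tested, and the threshold was 0.05. With 2 libraries per group an exact permutation test could not reach the threshold, so p-values come from this model only.

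A set of 38 gene lists was fixed before the data were examined. Lists with at least 3 tested members were tested with camera at a preset correlation of 0.01, and again with an estimated correlation and with fry. This held for 35 lists. Counts of members past the threshold are given over all genes tested and adjusted over the list alone. Named genes follow a rule that was fixed before the data were examined. It takes up to 10 genes per direction for all induced cells against PBMC and for GFP-positive against GFP-negative cells, and 5 for each induced group against PBMC. These are the largest changes among genes past the threshold whose groups did not overlap and whose higher group averaged at least 10 FPKM. It further takes up to 4 members per list, the 2 with the largest change and the 2 with the highest mean, and always a set of neurogenic factors that includes POU3F2, MYT1L and NEUROG2. Other genes are said to have been chosen after their values were seen. Immune receptor segments, genes of the Y chromosome and genes often deleted in single people are not named. Some genes that the rule takes are not reported here.

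The fit was tested on simulated data of 13544 genes with the residual spread of each gene, set equal in all groups. Estimated changes followed the known ones with slopes between 0.945 and 1.01. With 200 changed genes, 0% of the 2-fold and 0% of the 4-fold changes passed the threshold in each of the 4 comparisons. A second simulation, added after that result was seen, changed 6772 genes. In it 37.5% of 2-fold and 75.0% of 4-fold changes were recovered for all induced cells against PBMC, with 3.10% of calls false. For GFP-positive against GFP-negative cells the values were 25.7%, 65.4% and 2.68%. Simulated changes of 2-fold and 4-fold therefore passed only where many genes changed together, and larger changes were not simulated. A gene that does not pass is not shown to be unchanged. The measured GFP-negative libraries were less alike (Pearson's r 0.904) than those of PBMC (0.981) and GFP-positive cells (0.973). The simulations leave this out, so their shares of recovered and false calls may not hold for contrasts with GFP-negative cells. Alternatives were pseudocounts of 0.1 and 5, no filter or a filter of 5 FPKM, quantile and median-ratio scaling, genes with a 0 left out, other priors, only the groups compared, a minimum change of 1, a replicate block, and each library left out in turn.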

Results

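Gene expression was measured by RNA sequencing in PBMC, in PSA-NCAM-positive GFP-positive cells and in PSA-NCAM-positive GFP-negative cells, with 2 libraries in each group. The GFP-positive and GFP-negative groups are called induced cells here, as in the labels. FPKM summed to 570600 and 549300 in PBMC, 435500 and 387400 in GFP-positive cells, and 780900 and 500500 in GFP-negative cells. Genes listed at 0 numbered 7265 and 6886 in PBMC, 8108 and 7069 in GFP-positive cells, and 11580 and 10140 in GFP-negative cells. Across the 13544 genes tested, Pearson's r of log2(FPKM + 1) between the libraries of a group was 0.981 in PBMC, 0.973 in GFP-positive cells and 0.904 in GFP-negative cells. Genes are not independent replicates. Between groups r lay between 0.573 and 0.728.

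The first comparison asked how the transcriptome of induced cells differed from that of PBMC, the starting population. Whether the PBMC and induced libraries share donors is not given in the sources used here. A difference between donors therefore cannot be told apart from one between PBMC and induced cells. Neuronal genes were higher and lymphocyte genes lower in induced cells. The neuronal tubulin TUBB3 rose from 0.436 and 0.229 FPKM in PBMC to 466 and 400 in GFP-positive and 57.0 and 59.0 in GFP-negative cells (log2 change 6.91, SE 0.22, adjusted p = 8.8e-05). The cytotoxic granule protease GZMB fell from 7148 and 8425 FPKM to between 0.177 and 4.95 (log2 change -11.52, SE 0.46, adjusted p = 0.00013). In all, 3566 genes were higher and 4009 lower among 13544. Leaving out the unnumbered PBMC library gave 3167 genes in place of 7575, and leaving out PBMC replicate 2 gave 3548, in each case with PBMC as a lone library assumed to vary like the other groups.

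Among the largest increases were those in CKB (brain creatine kinase), CPE (a prohormone-processing enzyme), CRYAB (a small heat shock protein), TSPAN7, SPARC (a matrix glycoprotein), GPM6B (a neural membrane proteolipid), HIST3H2A, HIST1H2BE and the record MIR3661. CKB rose from 8.42 and 9.91 FPKM to 4556 and 2834 in GFP-positive and 6507 and 4929 in GFP-negative cells, and CPE from under 0.05 FPKM in PBMC to between 311 and 567. Histone genes share near-identical sequence, and the record MIR3661 can overlap other transcripts, so reads of these cannot be assigned with certainty. The largest decreases were in GZMB, IFNG (interferon gamma), IL17F, GNLY (granulysin), IL8, CCL3, CCL4, CCL3L3, CCL4L1 and CCL4L2. IFNG stood at 3798 and 1767 FPKM in PBMC and at 0, 0.636, 2.68 and 6.87 in induced libraries. The CCL3 and CCL4 genes are near-identical copies, and their single values are uncertain.

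Of the 18 tested pan-neuronal genes 18 rose, among them STMN2 (log2 change 6.46) and ENO2 (1.81). Of 19 genes of synaptic vesicles and release 18 rose, including SNAP25 (6.07) and VAMP2 (3.37). All 17 tested neurogenic transcription factors rose in the mean of both induced groups, 16 of 17 in GFP-positive cells alone (17 adjusted over the list alone) and 7 of 17 in GFP-negative cells alone, as did 10 of 10 neural progenitor genes in that mean, with SOX2 at 6.91 and FABP7 at 5.88. Rises in that mean were also counted for 10 of 11 glutamate receptor and postsynaptic genes (CAMK2B, 3.63), 7 of 7 GABAergic (CALB2, NPY), 7 of 8 voltage-gated channel, 11 of 11 axon guidance (NRCAM) and 8 of 8 neuronal splicing genes (NOVA1). Of 8 glutamatergic identity genes 7 rose, such as NEUROD6 and CUX1, and EOMES, also a gene of cytotoxic lymphocytes, fell. The calls for CALB2 (log2 change 4.25) and EOMES (-2.93) were lost when either PBMC library was left out. Adjusted over the list alone, the counts were the same except for 19 synaptic vesicle and 8 channel genes. Camera with the preset correlation called each of these 10 lists up, with adjusted p between 5.4e-08 and 0.0033. With an estimated correlation no list passed (adjusted p = 0.132 to 0.190 for these lists). The glutamatergic call was lost with genes at 0 left out. Against PBMC, the median log2 change of neural progenitor genes was 3.35 in GFP-negative and 2.50 in GFP-positive cells. Astrocyte genes had the same order (4.04 and 3.29), and pan-neuronal genes the reverse (1.01 and 4.29). Whether the glia culture contributed to the progenitor genes was not tested.

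POU3F2, MYT1L and NEUROG2, transcription factors that drive neuronal fate, were close to 0 in PBMC. POU3F2 reached 194 and 142 FPKM in GFP-positive and 3.49 and 3.73 in GFP-negative cells. NEUROG2 stood at 146 and 265 FPKM in GFP-positive and 0 and 1.56 in GFP-negative cells, and MYT1L at 15.0 and 16.4 against 0 and 0.061. In GFP-negative cells against PBMC neither passed (adjusted p = 0.333 for NEUROG2 and 0.896 for MYT1L). Which genes the vectors carried is not given in the sources used here, and FPKM do not separate vector from endogenous transcripts.

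**Figure D1:**
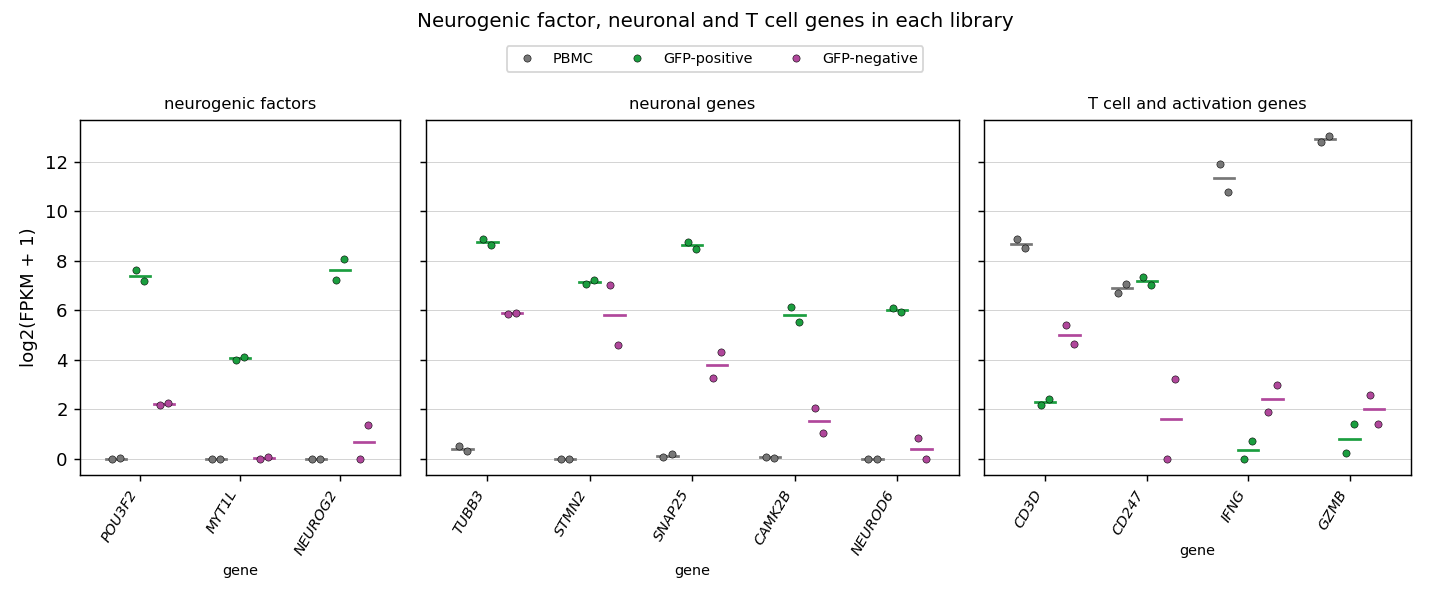
Expression, as log2(FPKM + 1), of neurogenic factors, neuronal genes and T cell genes (horizontal axis) in the 2 libraries of each group (points) with their mean (bars). TUBB3 and SNAP25 are highest in GFP-positive cells, CD3D, IFNG and GZMB in PBMC, and CD247 stands at 160 and 129 FPKM in GFP-positive cells.

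Blood genes moved the other way. T cell activation genes, GZMB and IFNG among them, were abundant in the PBMC libraries, and whether these had gone through the bead activation is not given in the sources used here. Falls of activation, cell cycle, interferon-stimulated and cholesterol synthesis genes are relative to these libraries. Of 23 tested T cell genes 20 fell and 0 rose, of 19 T cell activation genes 19 fell, and of 19 pan-leukocyte genes 19 fell. CD3D, a chain of the T cell receptor complex, fell from 462 and 364 FPKM to 3.51 and 4.27 in GFP-positive and 41.1 and 23.6 in GFP-negative cells. NK and cytotoxic genes fell in 11 of 12 (12 adjusted over the list alone), MHC class II genes in 9 of 9, B cell genes in 8 of 11 and monocyte genes in 11 of 15, with 2 monocyte genes higher, all in the mean of both induced groups. The counts of the other lists were the same adjusted over the list alone. Camera called the 7 lists down with adjusted p between 5.4e-08 and 0.0086. With an estimated correlation adjusted p was 0.132 for T cell, T cell activation and pan-leukocyte genes, 0.190 for NK genes, 0.395 for MHC class II, 0.487 for B cell and 0.536 for monocyte genes. The monocyte call was lost with a filter of 5 FPKM and with genes at 0 left out. Of 6 platelet and erythroid genes 2 fell, and camera did not call the list.

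Other groups differed as well. All 24 tested cell cycle genes fell, among them PCNA (560.9 and 332 FPKM in PBMC, 22.1 and 20.6 in GFP-positive, 76.3 and 66.5 in GFP-negative cells), and all 15 interferon-stimulated genes fell, such as IFIT3 and OAS2. Of 14 cholesterol synthesis genes 12 fell (14 adjusted over the list alone), with FDFT1 at a log2 change of -3.67. Of 20 cytosolic ribosomal protein genes 10 fell (9 adjusted over the list alone), and of 15 unfolded protein and amino acid stress genes 8 fell. Camera called these 5 lists down, with adjusted p between 3.0e-08 and 0.042, and with an estimated correlation adjusted p was 0.199, 0.256, 0.167, 0.550 and 0.350. Of 10 immediate-early genes 4 rose and 1 fell, with EGR1 at 5.51 and FOS at 5.13, and camera called the list up (adjusted p = 0.033, and adjusted p = 0.190 with an estimated correlation). In GFP-negative cells alone 6 immediate-early genes rose and 0 fell, and camera called the list up (adjusted p = 0.00095, and 0.230 with an estimated correlation). In GFP-positive cells alone 4 rose and 2 fell (3 adjusted over the list alone), and it did not (adjusted p = 0.515). Ribosomal protein genes fell in 13 of 20 in GFP-positive cells alone (16 adjusted over the list alone) and in 7 of 20 in GFP-negative cells alone (5 adjusted over the list alone), with camera adjusted p = 5.3e-05 (0.396 with an estimated correlation) and 0.368. Stress genes fell in 5 of 15 and in 7 of 15 with 1 higher (adjusted p = 0.012, 0.256 with an estimated correlation, and 0.312), and camera did not call them between the induced groups (adjusted p = 0.378). The stress call was lost without PBMC replicate 2, GFP-positive replicate 2 or GFP-negative replicate 2, and the immediate-early call without GFP-positive replicate 1 or 2. A pseudocount of 0.1, a filter of 5 FPKM and leaving out genes at 0 also ended the stress call. Using no filter also ended the immediate-early call. Camera did not call glycolysis (2 up, 6 down of 13), oxidative phosphorylation (3 up, 8 down of 16), p53 targets (5 up, 5 down of 13), non-neuronal repressors (2 up, 1 down of 5), the PSA-NCAM gate genes (2 up, 1 down of 3) or the widely expressed reference genes (3 up, 2 down of 11).

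Markers of other cell types moved with the induced groups. Of 13 tested astrocyte genes 11 rose and 1 fell: GFAP stood at 56.1 and 32.2 FPKM in GFP-positive and 109 and 79.8 in GFP-negative cells, against 0 and 0.0389 in PBMC. Fibroblast and matrix genes rose in 9 of 9 tested, oligodendrocyte lineage genes in 5 of 7 with 1 lower, and skeletal muscle genes in 3 of 4 (4 adjusted over the list alone). The full lists hold 16, 12 and 12 genes, and members left out by the filter were not tested. In examples chosen after their values were seen, MYOG, LUM, POSTN and GPR17 were listed at 0 in each library. MAG, also untested, stood at 4.55 and 0.869 FPKM in GFP-negative cells. Camera called these 4 lists up (adjusted p between 3.4e-05 and 0.025), and with an estimated correlation adjusted p was 0.165 for astrocyte genes and 0.190 for the other lists. The oligodendrocyte call was lost with a filter of 5 FPKM, and this and the muscle call with genes at 0 left out. In GFP-negative cells alone camera did not call oligodendrocyte lineage genes (5 higher, 1 lower, adjusted p = 0.083). Of 3 tested microglia genes 1 rose and 1 fell, and camera did not call the list. Monoaminergic, cholinergic and peripheral neuron genes had 2 tested members, too few for camera, of which ISL1 rose and SLC18A2 did not pass. The ISL1 call was lost without either PBMC or either GFP-positive library. The lists of pluripotency and mitochondrially encoded genes had 0 tested members.

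**Figure D2:**
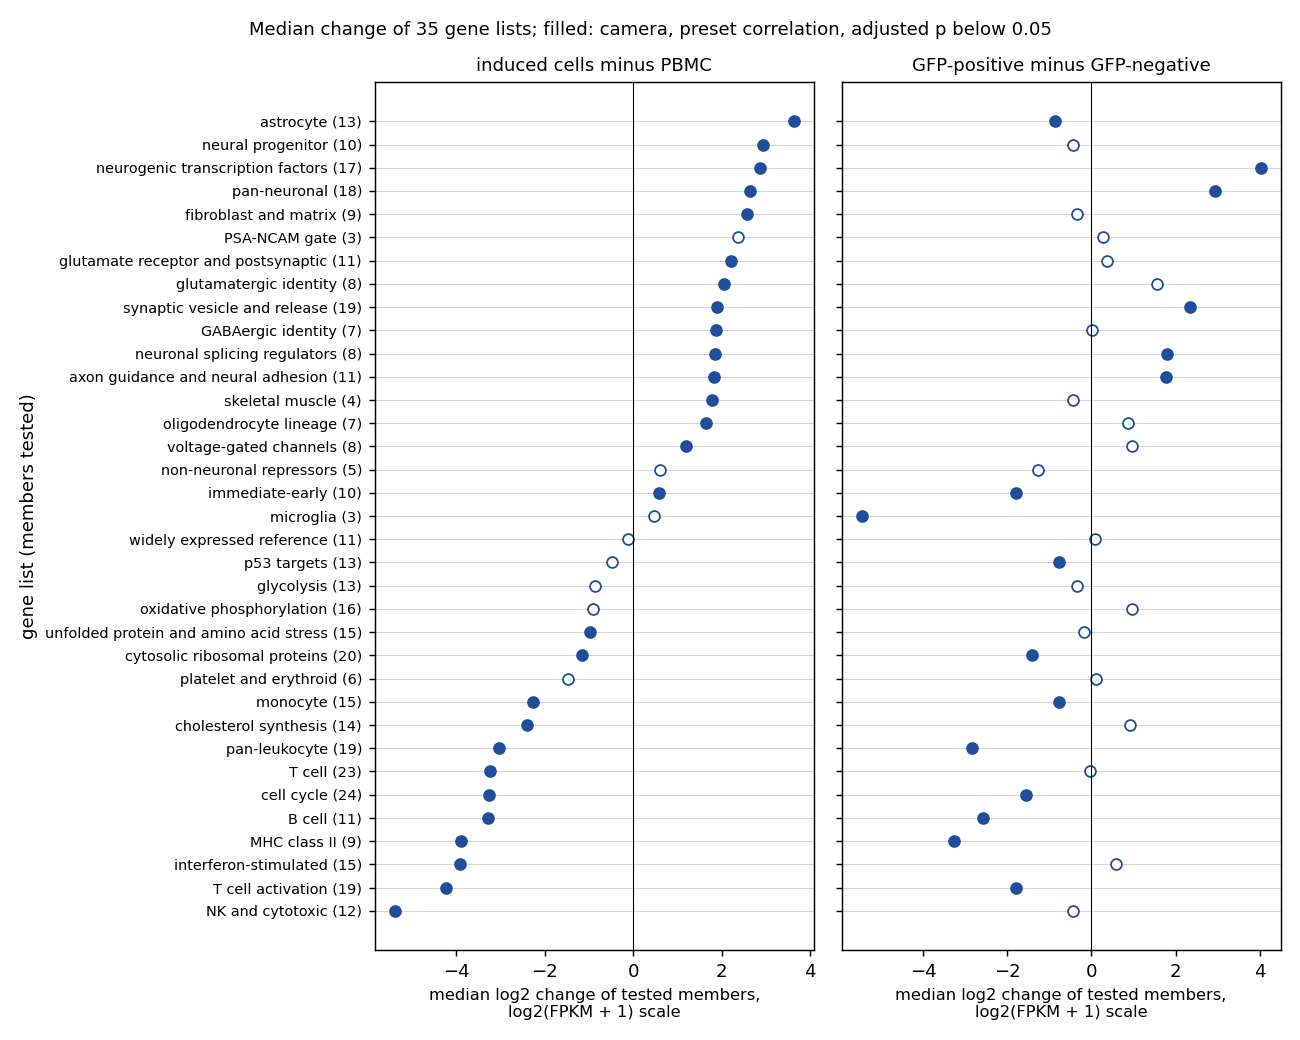
Median log2 change of the tested members of 35 gene lists (vertical axis, with the number of members) for induced cells minus PBMC and for GFP-positive minus GFP-negative cells (horizontal axes). Filled points mark lists called by camera with the preset correlation, 27 on the left and 16 on the right. No list was called with an estimated correlation.

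Against PBMC, GFP-positive cells had higher neuronal and lower T cell genes. All 18 pan-neuronal genes and 19 of 19 synaptic vesicle genes rose, as did 11 of 11 glutamate receptor, 7 of 8 channel, 11 of 11 axon guidance, 8 of 8 neuronal splicing, 9 of 10 neural progenitor and 5 of 7 GABAergic genes (6 adjusted over the list alone). Of 8 glutamatergic genes 7 rose and 1 fell. Camera called these 9 lists up (adjusted p between 6.4e-10 and 0.012), and with an estimated correlation adjusted p lay between 0.123 and 0.176. Among the largest increases were those in CPE, SNAP25 (log2 change 8.48), CKB (8.47) and TSPAN7 (8.43), and the largest decreases in GZMB (-12.11), CCL3 (-11.18), IFNG (-10.98), CCL4 (-10.43) and CCL4L2 (-9.60). T cell genes fell in 17 of 23 (18 adjusted over the list alone) and rose in 1 (2 over the list alone). MHC class II genes fell in 9 of 9, B cell genes in 8 of 11 (9 adjusted over the list alone) and monocyte genes in 12 of 15 (13 over the list alone), with 1 monocyte gene higher. Camera called these 4 lists down (adjusted p between 6.5e-07 and 0.00013), and with an estimated correlation adjusted p was 0.123, 0.301, 0.341 and 0.343. In total 3328 genes were higher and 3108 lower. Leaving out a library of either group lowered the count of 6436, to 3030 without the unnumbered PBMC library, 3325 without PBMC replicate 2, 3301 without GFP-positive replicate 1 and 3533 without GFP-positive replicate 2.

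Against PBMC, GFP-negative cells had fewer calls than GFP-positive cells in most neuronal lists, though not among GABAergic or neural progenitor genes. T cell genes were lower than in PBMC. Counts of calls do not test the difference between the induced groups. Of 18 pan-neuronal genes 8 rose and 10 did not pass, and of 19 synaptic vesicle genes 6 rose (5 adjusted over the list alone). Rises were counted for 8 of 11 glutamate receptor, 3 of 8 channel, 5 of 11 axon guidance (4 adjusted over the list alone), 3 of 8 neuronal splicing, 10 of 10 neural progenitor and 6 of 7 GABAergic genes. Of 8 glutamatergic genes 2 rose and 1 fell, with NEUROD6 at 0.774 and 0 FPKM (adjusted p = 0.392), and camera did not call the list (adjusted p = 0.171). Camera called the other 8 lists and the neurogenic factors up (adjusted p between 1.9e-05 and 0.024), and with an estimated correlation adjusted p lay between 0.230 and 0.327. T cell genes fell in 20 of 23 (21 adjusted over the list alone), and camera called them down (adjusted p = 1.1e-05, and 0.230 with an estimated correlation). MHC class II genes fell in 3 of 9, B cell genes in 5 of 11 (6 adjusted over the list alone) with 1 higher, and monocyte genes in 8 of 15 with 3 higher. Camera called none of the last 3 lists in GFP-negative cells (adjusted p = 0.10, 0.223 and 0.312). The largest increases were in MIR3661 (log2 change 9.97), HIST3H2A (9.21), CKB (9.13), CRYAB (9.12) and HIST1H2BE (8.95), and the largest decreases in GZMB (-10.93), CCL4L2 (-9.60), IFNG (-8.91), CCL3L3 (-8.61) and CCL4 (-8.57). In total 3064 genes were higher and 4466 lower. The count of 7530 was 3494 without the unnumbered PBMC library and 3796 without PBMC replicate 2.

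Fold changes of the 2 induced groups against the same PBMC libraries correlated across 13544 genes (Pearson's r 0.638, Spearman's rho 0.612, same sign in 70.8%). Simulated unchanged groups of equal spread sharing 2 control libraries gave r 0.50, rho 0.457 and 66.7% over 100 draws. The covariance was 2.39 against 0.134 simulated, a difference of 2.26. Of the genes called, 1634 were higher in both groups, where independent lists of these sizes would share 753, and 2220 were lower in both, where they would share 1025. With each induced group set against a different PBMC library, an alternative chosen after seeing the data, r was 0.634 and 0.60, the covariance 2.38 and 2.30, and the same-sign share 69.9% and 70.2%. Each group then has 1 control library, and part of the excess in shared calls may come from the shared libraries. Opposite calls were made for 319 genes.

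The comparison within induced cells asked how the GFP-positive fraction differed from the GFP-negative one. Of 18 pan-neuronal genes 16 were higher in GFP-positive cells. Of 15 monocyte genes 6 were higher in GFP-negative cells, 1 was lower and 8 did not pass. SNAP25, a synaptic fusion protein, stood at 429.8 and 354 FPKM in GFP-positive and 8.52 and 18.9 in GFP-negative cells (log2 change 4.83, SE 0.40, adjusted p = 0.00091). LYZ, the lysozyme of myeloid cells, stood at 0.25 and 0.351 FPKM in GFP-positive and 502 and 248 in GFP-negative cells (log2 change -8.09, SE 0.56, adjusted p = 0.00075). In all, 3693 genes were higher and 2437 lower in GFP-positive cells. The count of 6130 was 2356 and 2176 without GFP-positive replicates 1 and 2, and 3711 and 3698 without the unnumbered PBMC library and PBMC replicate 2.

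Among the largest differences toward GFP-positive cells were those in HBD, TTC9B, NEUROG2, DLL3 (a Notch ligand), LDOC1, TMEM59L, ARSF, DUSP26 and LIN7B, with DLL3 at 869 and 575 FPKM against 6.63 and 5.41. TMEM59L (adjusted p = 0.0029) did not pass without GFP-positive replicate 1. Those toward GFP-negative cells were in CCL22 and CCL17 (chemokines of myeloid and dendritic cells), LYZ, AIF1, FCER1G, SPI1 (a myeloid transcription factor), CSF1R (the receptor of macrophage growth factor), UNC93B1, CCR7 and the record MIR223. CCL22 stood at 415 and 3952 FPKM in GFP-negative cells and SPI1 at 1013 and 748, against 6.98 and 1.89 for SPI1 in GFP-positive cells.

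In GFP-positive cells 16 of 18 pan-neuronal, 16 of 19 synaptic vesicle (17 adjusted over the list alone), 15 of 17 neurogenic transcription factor (16 adjusted over the list alone), 8 of 11 axon guidance and 6 of 8 neuronal splicing genes were higher than in GFP-negative cells. STMN4 (5.76), NEFL (5.33), SYT4 (4.24), CNTN1 (3.99) and CELF4 (3.20) are examples. Camera called these 5 lists up (adjusted p between 1.1e-06 and 0.039), and with an estimated correlation adjusted p was 0.201, 0.257, 0.201, 0.567 and 0.378. The axon guidance call was lost without either PBMC or either GFP-negative library, and the splicing call without either PBMC library or GFP-negative replicate 2, with adjusted p of 0.092 or less. Both were also lost with a pseudocount of 0.1, a filter of 5 FPKM and only the induced groups in the fit. The replicate block ended both calls too (camera adjusted p = 0.052 each), and leaving out genes at 0 ended that for axon guidance (0.294). Glutamatergic identity genes were higher in 5 of 8, NEUROD6 and NEUROD2 among them, and camera did not call the list (adjusted p = 0.067, and 0.037 without GFP-positive replicate 2). GABAergic genes were higher in 0 and lower in 1 of 7, NPY at 54.4 and 65.5 FPKM in GFP-negative cells. Camera also did not call glutamate receptor (5 up, 1 down of 11), channel (4 up, 2 down of 8), neural progenitor (1 up, 1 down of 10) or PSA-NCAM gate genes (1 up of 3). ISL1 and SLC18A2, the 2 tested monoaminergic, cholinergic and peripheral neuron genes, were higher in GFP-positive cells, and the ISL1 call (adjusted p = 0.021) was lost with a pseudocount of 0.1, without a filter, with only the induced groups in the fit and without either PBMC or either GFP-positive library.

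Pan-leukocyte genes were lower in GFP-positive cells in 13 of 19 (14 adjusted over the list alone), T cell activation genes in 10 of 19, B cell genes in 7 of 11, MHC class II genes in 6 of 9 (8 adjusted over the list alone), monocyte genes in 6 of 15 with 1 higher, and microglia genes in 2 of 3. LCP1 stood at 15.5 and 14.5 FPKM in GFP-positive and 492 and 397 in GFP-negative cells. Cell cycle genes were lower in 13 of 24 (14 adjusted over the list alone), immediate-early genes in 7 of 10, p53 targets in 5 of 13, ribosomal protein genes in 10 of 20 with 1 higher, and astrocyte genes in 3 of 13 (0 adjusted over the list alone). Camera called these 11 lists down (adjusted p between 1.1e-06 and 0.049), and none with an estimated correlation, where adjusted p lay between 0.201 and 0.698. Under quantile scaling the calls for axon guidance, neuronal splicing, astrocyte, microglia, p53 target and ribosomal protein genes were lost. The microglia call was also lost without any 1 library other than GFP-positive replicate 1, and with either pseudocount or only the induced groups in the fit. The p53 call was also lost without either PBMC library or GFP-negative replicate 2. A filter of 5 FPKM, genes at 0 left out and only the induced groups in the fit ended it too. The astrocyte call was also lost without GFP-positive replicate 2 or either GFP-negative library. A pseudocount of 0.1, a filter of 5 FPKM and genes at 0 left out ended it too. T cell genes went both ways, 5 higher and 6 lower of 23: CD247, the zeta chain of the T cell receptor complex, stood at 160 and 129 FPKM in GFP-positive and 0 and 8.31 in GFP-negative cells, against 104 and 132 in PBMC. Camera did not call T cell genes, NK genes (2 lower of 12), platelet and erythroid genes (0 of 6), oligodendrocyte lineage (3 higher of 7), fibroblast and matrix (3 higher, 2 lower of 9), muscle (1 higher, 1 lower of 4), stress (2 higher, 5 lower of 15), interferon-stimulated (2 higher, 1 lower of 15), glycolysis (2 higher, 2 lower of 13), cholesterol synthesis (7 higher, 1 lower of 14), non-neuronal repressor (3 lower of 5) or reference genes (1 lower of 11). Oxidative phosphorylation genes (7 higher, 2 lower of 16) were called under 1 of the alternatives run, quantile scaling (adjusted p = 0.0025). The CD247 difference (adjusted p = 0.0063) did not pass without either GFP-positive library.

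**Figure D3:**
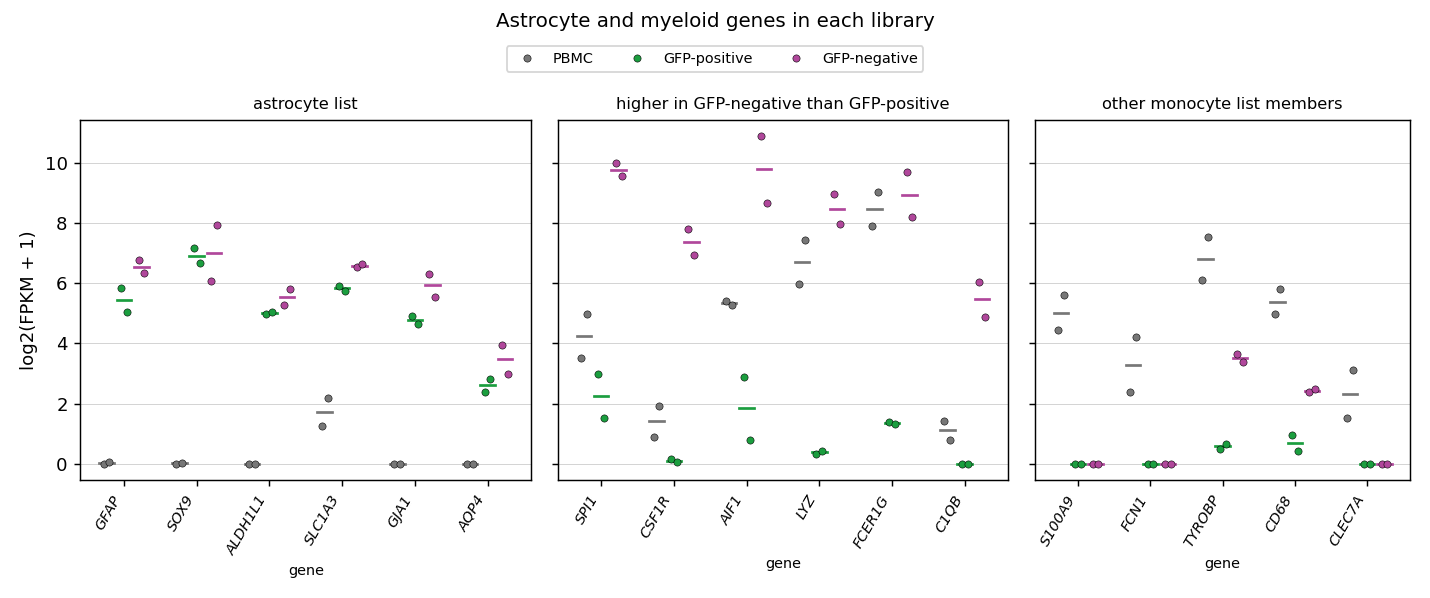
Expression, as log2(FPKM + 1), of astrocyte genes, of genes higher in GFP-negative than GFP-positive cells and of other monocyte list members (horizontal axis) in the 2 libraries of each group (points) with their mean (bars). SPI1 and CSF1R are highest in GFP-negative cells, while S100A9 and FCN1 are listed at 0 in each induced library.

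Scaling shifted the median change of all genes. It was -0.16 for induced cells against PBMC and -0.03 after quantile scaling, -0.32 and -0.08 for GFP-negative cells against PBMC, and 0.15 and -0.08 for GFP-positive against GFP-negative cells. For GFP-positive cells against PBMC it was -0.04 and, with median-ratio scaling, 0.10. The split of calls moved as well. After quantile scaling 3983 genes were higher and 3831 lower in induced cells against PBMC, 3600 and 3854 in GFP-negative cells against PBMC, and 3335 and 3163 in GFP-positive against GFP-negative cells. With genes at 0 left out, the last 2 splits were 2820 against 3145 and 2381 against 2368, and GFP-positive cells against PBMC had 2292 higher and 2339 lower. Without GFP-positive replicate 1 or 2, 73.2% and 74.0% of the calls between the induced groups were higher in GFP-positive cells, in place of 60.2%. Median, mean and camera direction differed in sign for microglia, p53 target and reference genes in induced cells against PBMC, and for p53 target and reference genes in GFP-negative cells against PBMC. They also differed for GABAergic, T cell, fibroblast and matrix, platelet and erythroid, interferon-stimulated and reference genes in GFP-positive against GFP-negative cells. Camera called none of these lists there.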

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

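The tests of explanations below were chosen after the results they measure were seen, except the sum over histone genes. For 7 named genes the 2 induced groups were called in opposite directions against PBMC, and the difference between the groups itself passed the threshold in limma. AIF1, LYZ, SPI1, UNC93B1, LDOC1 and LIN7B were named for a large difference between the groups. All 319 genes with opposite calls had a called difference. The passing differences, also those with a library left out, are thus no added support. AIF1 (GFP-positive minus GFP-negative -7.94), LYZ (-8.09), SPI1 (-7.50), UNC93B1 (-7.08) and ZFP36 (-4.29) were lower than in PBMC in GFP-positive cells and higher in GFP-negative cells. LDOC1 (6.55) and LIN7B (6.23) went the other way. These 2 differences depended on the pseudocount, at 9.86 and 9.53 with 0.1 and at 4.29 and 3.98 with 5. Against PBMC, the LDOC1 call in GFP-negative cells was lost with 5 (limma adjusted p = 0.080). That of SPI1 in GFP-positive cells was lost with either pseudocount, and that of LYZ in GFP-negative cells with 0.1. With any 1 library left out, each difference between the groups passed. Calls against PBMC that only just passed were those of SPI1 in GFP-positive cells (adjusted p = 0.048), LYZ in GFP-negative cells (0.038) and AIF1 in GFP-positive cells (0.022), each lost in 4 of 6 such fits, with highest adjusted p of 0.281, 0.207 and 0.164. The ZFP36 call in GFP-positive cells was lost in 3 of 6, and in GFP-negative cells that of AIF1 in 2 and that of LDOC1 in 1.

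Of 15 tested monocyte list members 3 were higher in GFP-negative cells than in PBMC (CSF1R, SPI1 and LYZ, the last only just), while 8 were lower. Blood monocytes left over with the profile they have in PBMC would move these genes by about the same factor, provided monocytes gave their PBMC values. Under that condition the 8 lower members argue against such cells as the whole source. Which cells gave the PBMC values was not measured, and CD14 was low there (0.994 and 2.41 FPKM). Monocytes that changed their profile in culture could give 3 higher beside 8 lower members and stay open, since no such cells were measured. Microglia or macrophages of the glia culture could be a source, but 2 of 8 microglia genes were above 1 FPKM in both GFP-negative libraries (AIF1 and C1QB), with C1QC and TREM2 listed at 0. A PSA-NCAM sort would remove cells without that marker, no genome of the glia was used here, and reads of another species would be assigned unevenly, so these cannot be told apart from expression by the sorted cells, which was not tested.

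Astrocyte genes were higher in both induced groups than in PBMC for 11 of 13 tested members. Even carry-over of all GFP-negative cells into the GFP-positive sort would lower these genes and 5 monocyte and microglia list members alike. These 5 were picked because they rose in the same GFP-negative libraries. Their median lay below that of the astrocyte list by a log2 difference of -6.64, which argues against even carry-over only. Carry-over of just those GFP-negative cells that hold astrocyte genes could give the same gap and stays open. Cells or RNA of the primary glia may be the source, as 11 members rose together, among them GFAP, ALDH1L1 and GJA1, although SLC1A2 (0.691 and 0.743 FPKM in GFP-positive cells) and AGT (0 and 0.0474) stayed low. Which culture steps the PBMC libraries went through is not given in the sources used here, and no induced group was kept off the glia, as far as the labels say, so glia and expression by the induced cells cannot be told apart. The PSA-NCAM sort applies here too.

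Of 60 tested histone genes 33 were higher in induced cells than in PBMC and 11 lower. More dividing cells were argued against by the cell cycle list, of which 24 of 24 tested members fell. With median-ratio scaling the median change of the tested histone genes was 1.59. The factors of the libraries lay between 0.9475 and 1.087. Factors this alike could not have removed a change of that size, so this fit does not decide on scaling of the libraries. Reads moved between near-identical copies stay open: the lowest sum of histone FPKM in an induced library was 0.40 times the highest in PBMC, with sums of 3880 and 2831 in GFP-positive, 16080 and 7874 in GFP-negative cells, and 7069 and 4756 in PBMC. A change of histone transcripts with cell state was not tested.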

How the results depend on the processing

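Of 123 recomputed counts and correlations, 106 stayed within the spread or within 1.5 times. With only the groups compared in the fit, 3737 genes passed for GFP-positive against GFP-negative cells. The count rose to 9017 for GFP-positive and fell to 5930 for GFP-negative cells against PBMC. Median changes were the same as in the fit of all groups, so the counts moved with the estimated spread and its degrees of freedom. GFP-negative libraries were less alike (Pearson's r 0.904) than those of PBMC (0.981) and GFP-positive cells (0.973). A shared spread can thus make p-values too small in contrasts with GFP-negative cells, and too large for GFP-positive cells against PBMC. With a replicate block on the induced libraries 3123 genes passed between them, and camera no longer called axon guidance and neuronal splicing genes (adjusted p = 0.052 each). The numbers were not taken to pair libraries, since the labels do not say that they mark a donor, and the descriptions of only the replicates 2 share a number. With 2 libraries per group deviations mirror each other, so their correlation of 0.0888 does not test that pair. A block against PBMC was not run, because the column of 1 PBMC library does not match the number in its label. With estimated correlations 0 lists passed in either comparison (8 and 6 of 35 at an unadjusted p under 0.05), and fry called 31 and 22. With a library left out, counts ranged from 3167 to 9618 for all induced cells against PBMC, 3030 to 9006 for GFP-positive and 3494 to 9341 for GFP-negative cells against PBMC, and 2176 to 8624 for GFP-positive against GFP-negative cells. The correlation ranged from 0.582 to 0.654. Without both the unnumbered PBMC library and GFP-negative replicate 1, an alternative chosen after seeing the data, these counts were 5837, 5597, 5270 and 4523. Of 4871 recomputed changes of named genes, 4455 kept direction and side of the threshold, 332 no longer passed and 56 newly passed. A further 27 changed sign or reached 0 without passing under either setting, and 1 reversed with a call. This was SOX9 (GFP-positive minus GFP-negative), at 0.85 without GFP-negative replicate 2 and -1.005 without GFP-negative replicate 1. SOX9 stood at 66.3 and 242 FPKM in GFP-negative replicates 1 and 2. Its GFP-positive values (143 and 101) lay between these, so the sign depended on which replicate was left out. Depth is unknown, so it cannot be said which low values it limits.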

Other observations

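Genes named in this paragraph without a list were chosen after their values were seen. Some genes departed from their usual partners. HBD, a globin gene, stood at 246 and 216 FPKM in GFP-positive cells while HBB was listed at 0 in both. COL1A2 stood at 73.9 and 76.6 FPKM and DCN at 31.9 and 26.7 in GFP-positive cells, while COL1A1 was at 2.39 and 0.609 and COL3A1 at 0 and 0.0194. CD4 was at 33.5 and 30.4 FPKM in GFP-positive cells, against 9.02 and 11.8 in PBMC and 6.92 and 9.16 in GFP-negative cells. HPRT1, a widely expressed reference gene, stood at 1494 and 549 FPKM in GFP-negative cells and at 70.3 and 66.5 in GFP-positive cells.

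The median T cell list member stood at 6.46% and 7.24% of its PBMC mean in GFP-positive libraries and 7.99% and 8.98% in GFP-negative libraries. For T cell activation genes the medians were 0% and 0.0208% against 3.75% and 4.55%. Medians of other lists were higher in GFP-negative libraries. Pan-leukocyte genes stood at 22.3% and 28.4% against 3.57% and 4.37% in GFP-positive libraries, and MHC class II genes at 16.6% and 39.3% against 0.224% and 0.663%. B cell genes stood at 9.89% and 54.0% against 0% and 0.179%, and monocyte genes at 9.86% and 10.8% against 0.214% and 0%. For NK and cytotoxic genes the medians were 0.813% and 0.439% against 0% and 0.387%. Single members stood above PBMC, such as SPI1 and CSF1R in GFP-negative cells. Whether any of these transcripts were left over from blood cells was not tested.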
